A study of Mus musculus with 8 samples.

How the data were processed

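Total RNA from the hearts of 4 wild type and 4 HDAC3-deficient male mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels' protocols, hearts were frozen at collection, RNA was extracted with Trizol and mice ate normal chow. The deposited table holds 1 processed value per transcript cluster and array, for 27541 clusters on 8 arrays. Per the submitters' processing notes, Partek and RMA (robust multi-array averaging, which corrects background, normalises between arrays and summarises probes) were used, with no version or role given. RMA output is usually on a log scale, but the deposited values are intensities on a linear scale, as their range on each array showed (for example 3.57 to 15357 on the first WT array). Whether they were rescaled or corrected in another way, and the probe annotation and genome build behind them, are not given in the sources used here. The scanner files were not analysed here, so no detection calls, scan dates or hybridisation batches could be examined, and a batch that follows the groups would not be seen. No further normalisation was applied in the main analysis. The array medians were 54.4, 54.3, 54.3 and 54.9 in WT and 55.6, 55.3, 54.1 and 56.5 in KO.

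Clusters were named through the platform annotation. Exactly 1 gene symbol was paired with 21631 clusters, several with 1317 and none with 4593. The Entrez ID of 21544 single-gene clusters was found in a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only and updated 0 symbols. Of 19933 genes, 951 had more than 1 cluster, and the cluster with the highest mean over all arrays was kept. Genes under the 25th percentile of mean level (log2 4.50, intensity 22.6) were left out, which removed 4983 genes and left 14950. The filter used all 8 arrays without regard to group. Genes without a cluster of their own, Cpt1b among them, were not analysed here.

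Groups were compared on log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 residual degrees of freedom), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 38 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, served as alternatives. Counts per list are given over all genes and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

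The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named Hdac3, the 12 largest rises and 12 largest falls among changed genes without overlap of the groups, up to 4 members of each list with the smallest p (at most 2 where no member changed), and a short set of cardiac and metabolic genes. Any other gene is said to be named after its values were seen.

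The test was run on simulated data before use: of 14950 genes, 100 were given 1.5-fold and 100 2-fold changes at the observed spread. It recovered 92% of 1.5-fold and 97% of 2-fold changes, made 12 false calls (5.97% of its calls) and called 0 of 37 unchanged lists. The lists were simulated without correlation between genes. Alternatives were other scalings between arrays, other filters on dim genes, another variance model, array weights, other handling of clusters, stricter thresholds, the replicate number as a block and leaving out each array in turn.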

Results

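Whole hearts of 8 male C57BL/6 mice aged 6 weeks were profiled on Affymetrix Mouse Gene 1.0 ST arrays, which read each gene through probes spread along its transcript. Of these mice 4 were wild type (WT) and 4 were deficient in HDAC3 (KO). HDAC3 is a histone deacetylase that works with nuclear receptor corepressors. The titles number the hearts as biological replicates, so each array stands for 1 mouse. The labels do not state in which heart cells the gene was removed. The median intensity of the 8 arrays lay between 54.1 and 56.5, and Pearson correlations across transcript clusters (the array's gene-level probe sets) were 0.993 to 0.996 among WT arrays, 0.995 to 0.998 among KO arrays and 0.989 to 0.992 between the groups. These correlations are across clusters within pairs of arrays, and clusters are not independent replicates. No pair of arrays held identical values. All differences are KO minus WT on the log2 scale with n = 4 arrays per group, and the number of arrays limits their precision.

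The targeted gene was examined before all others. Hdac3 (transcript cluster 10458461) was 10.10 ± 0.08 in WT and 8.57 ± 0.05 in KO hearts (mean log2 intensity ± SD, n = 4). It fell by 1.54 on the log2 scale (SE 0.05, 95% interval -1.66 to -1.42), to 34.4% of the WT level, with a Benjamini-Hochberg adjusted p of 9.19e-08 in limma. WT arrays ranged from 10.04 to 10.20 and KO arrays from 8.50 to 8.59, so every array matched its label. Which exons were deleted is not given in the sources used here, and the position of the probes relative to them was not checked.

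The main comparison asked which transcripts differ between hearts with and without HDAC3. Among the gene lists fixed beforehand, 19 of 20 macrophage and neutrophil markers, 11 of 26 genes of the amino acid stress response and 10 of 26 of the antioxidant response rose in KO hearts, as did a slow skeletal muscle troponin. Of calcium handling and ion channel genes 24 of 41 fell, and of tricarboxylic acid cycle genes 10 of 20. Of 14950 genes tested, 3683 (24.6%) changed at an adjusted p under 0.05, 1612 higher and 2071 lower. Most changes were small: 359 of the higher and 251 of the lower genes differed at least 1.5-fold, and 125 and 55 at least 2-fold. KO and WT values did not overlap for 3406 of the changed genes, and for 28.6% of all genes tested, where chance gives 2.86%. The median difference of all genes was -0.01.

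Tnnt1, the slow skeletal muscle isoform of troponin T, rose by 3.49 (SE 0.10, adjusted p = 3.29e-08, limma), from 6.55 ± 0.06 to 10.04 ± 0.22 (SD, n = 4). The 12 largest rises also held genes of the membrane proteins Ms4a4a (2.11), Ms4a6d (1.99), Ms4a6c (1.87) and Ms4a6b (1.83), the chemokine Ccl6 (1.84), the secreted protein Retnla (1.86), the RNA sensor Tlr8 (1.80), the Fc receptor-like gene Fcrls (1.73) and the complement receptor Vsig4 (1.71, SE 0.41). The Ms4a6 genes are close relatives, and hybridisation shared between them was not excluded. Of these genes Vsig4 varied most within WT (SD 0.96), and its adjusted p was 0.0124 with limma's standard variance model and 0.0526 with an intensity trend and robust variances, within a range of 0.00484 to 0.0526 over the alternatives. The remaining large rises were Nqo1 (1.87, SE 0.06, adjusted p = 7.34e-08), a quinone reductase induced by oxidative stress, and Mthfd2 (1.85, SE 0.10), an enzyme of mitochondrial folate metabolism.

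Scgb1c1, a secretoglobin, had the largest fall, from 9.73 ± 0.12 to 6.70 ± 0.06 (SD, n = 4), or -3.03 (SE 0.07, adjusted p = 7.62e-09, limma), which made it 8.15-fold lower. The orphan receptor gene Gpr22 fell by 2.51 on the log2 scale (SE 0.08), the ephrin gene Efnb3 fell by 2.15 and the growth factor gene Fgf16 fell by 2.06. Cabcoco1 (-1.98), the oxoglutarate dehydrogenase-like gene Ogdhl (-1.87), the amino acid transporter gene Slc36a2 (-1.81), the glycosyltransferase gene B3galt2 (-1.77) and the fatty acid desaturase gene Scd4 (-1.72) followed. The other members of the 12 largest falls were the channel genes Kcnip2 (-1.74), Kcne1 (-1.73) and Hcn2 (-1.72).

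**Figure D1:**
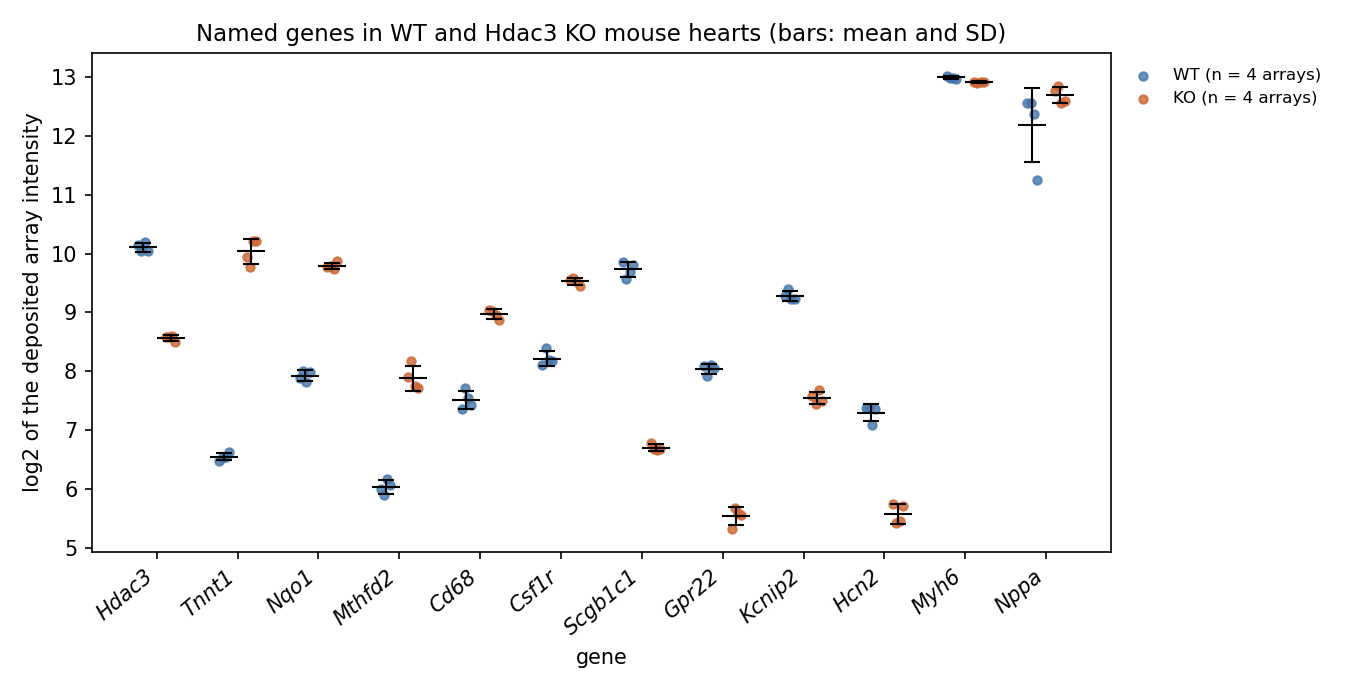
Log2 intensity of 12 named genes (horizontal axis) in each WT (blue) and KO (orange) heart, with the mean and SD of 4 arrays per group in black. Hdac3, Scgb1c1, Gpr22, Kcnip2 and Hcn2 are lower and Tnnt1, Nqo1, Mthfd2, Cd68 and Csf1r higher in all KO arrays, while Myh6 and Nppa differ by -0.08 and 0.51 and did not pass the test.

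Of 39 gene lists fixed before the data were examined, 38 had at least 5 measured members. With limma's camera test at a preset correlation of 0.01 between genes, 15 lists were shifted at an adjusted p under 0.05, 10 upward and 5 downward. The lists that also passed with an estimated correlation were 6: the macrophage, inflammation, amino acid stress, antioxidant, calcium and channel, and tricarboxylic acid cycle lists, each at an adjusted p of 0.0421. Other divisions of the 8 arrays shifted up to 21 lists at the preset correlation, so a count of 15 is not beyond what such divisions gave. The 5 others with as many lists each kept 3 arrays of a group together, and so still held part of the group difference. The 18 divisions with 2 arrays of each group on each side shifted at most 9 lists. With fry, which asks whether a list's genes move on balance one way and sets them against no other genes, 23 lists passed. The lists that passed with fry but not with camera were, downward, adult sarcomere (0.000317), deacetylases (0.000385), thyroid hormone and liver X receptor (0.002), cholesterol (0.00269), PPAR alpha (0.0039) and glycolysis (0.0116), and, upward, fetal and stress genes (0.00587), triglyceride (0.0116) and erythroid and platelet markers (0.0472). The deacetylase list holds the targeted gene Hdac3 itself, and its result without Hdac3 was not computed. Other lists also hold a single gene with a large change. These are Myom2 (sarcomere), Hcn2 (thyroid hormone and liver X receptor), Hsd17b7 (cholesterol), Fitm1 (PPAR alpha), Tnnt1 (fetal and stress) and Pf4 (erythroid and platelet). Their fry results without these genes were not computed either, so a direction shared by the members is not shown. The fibroblast list did not pass with fry (0.0957).

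Markers of macrophages and neutrophils were the most strongly shifted list. Of 20 measured members, 19 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 4.65e-19). Adgre1, an adhesion receptor gene that marks macrophages, rose by 1.54 (SE 0.09), the lysosomal gene Cd68 by 1.46 (SE 0.08), the lysozyme gene Lyz2 by 1.41 (SE 0.07) and Csf1r, the receptor gene for macrophage growth factors, by 1.31 (SE 0.07). The member that did not pass was the neutrophil gene S100a9 (0.11), named after its values were seen. Among lymphocyte markers 5 of 13 rose and 0 fell (5 and 0 adjusted over the list alone), with an adjusted p of 0.00112. This became adjusted p = 0.195 with an estimated correlation. The risers were Ptprc (1.04), present on all leukocytes, H2-Ab1 (1.04), H2-Aa (1.03) and Cd74 (1.04), which serve antigen presentation in macrophages and B cells, and Cd4 (0.42). The T cell gene Cd3e (0.04) and the B cell gene Cd79b (-0.04) did not pass. Cd4, Cd3e and Cd79b were named after their values were seen.

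Inflammation genes moved with the macrophage markers: 14 of 31 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 2.43e-06). Besides Ccl6, they included the chemokine Ccl7 (0.96), the lipopolysaccharide co-receptor Cd14 (0.77) and the interleukin 6 receptor gene Il6ra (0.76). In the interferon response list 12 of 23 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.30. The list's adjusted p was 7.01e-07, and adjusted p = 0.489 with an estimated correlation. Its mean over members, relative to WT, was 0.12 in KO replicate 4, below the 0.20 of WT replicate 2, and 0.38 to 0.53 in the other KO hearts. Oas2 rose by 0.76, Usp18 by 0.68, B2m by 0.30 and Psmb8 by 0.29. In the cell cycle list 16 of 29 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 0.37. The list's adjusted p was 2.43e-06, and adjusted p = 0.43 with an estimated correlation. Mcm7, part of the replicative helicase, rose by 0.43, the mitotic checkpoint gene Bub1b by 0.39 and Pcna by 0.37. Pcna did not pass when its clusters were averaged (0.28, adjusted p = 0.202, within a range of 4.12e-05 to 0.202 over the alternatives). The falls were Ccnd2 (-0.77), a cyclin of the G1 phase, and Cenpf (-0.70), named after its values were seen. The macrophage markers, with a median of 1.30, were higher in the same KO hearts as all these groups.

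Among extracellular matrix genes 14 of 42 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.21. The list's adjusted p was 2.43e-06, and adjusted p = 0.489 with an estimated correlation. Macrophage markers rose by a median of 1.30 in the same hearts. The thrombospondin Thbs4 rose by 1.28 (SE 0.10), Ccn2, a matricellular growth factor gene, by 1.19 (SE 0.12), tenascin C (Tnc) by 1.02 and Tgfb3 by 0.57. Ltbp1 (-0.52) and Thbs2 (-0.34), named after their values were seen, fell. The fibrillar collagen gene Col1a1 differed by 0.23 (adjusted p = 0.0516, range 0.00374 to 0.135 over the alternatives). It passed in 7 of its 16 alternatives, among them array weights (0.30, adjusted p = 0.00374), quantile normalisation (0.25, adjusted p = 0.0159), an intensity trend with robust variances (adjusted p = 0.0304), the stricter dim filter (adjusted p = 0.0351) and the fits without WT replicate 2 (0.29, adjusted p = 0.00732) and without KO replicate 4 (0.26, adjusted p = 0.0468). Among fibroblast markers 5 of 19 rose and 0 fell (6 and 0 adjusted over the list alone), including periostin (Postn, 0.64), Mfap5 (0.55) and lumican (Lum, 0.38). This list's adjusted p was 0.0315, and adjusted p = 0.635 with an estimated correlation. It was 0.0599 without WT replicate 1, 0.0505 without WT replicate 3, 0.0504 without WT replicate 4 and 0.0736 without KO replicate 2. Its mean over members was 0.06 in KO replicate 4, below the 0.13 of WT replicate 2.

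Genes of the amino acid and integrated stress response rose, 11 of 26, against 1 that fell (13 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 1.7e-05). Beside Mthfd2, asparagine synthetase (Asns) rose by 1.28 (SE 0.11), the amino acid transporter gene Slc7a5 by 0.73 and the transcription factor gene Atf5 by 0.50, while Shmt2 (-0.17), named after its values were seen, fell. In the antioxidant response list 10 of 26 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 2.02e-05). Beside Nqo1, metallothionein 2 (Mt2) rose by 1.08 (SE 0.10), heme oxygenase 1 (Hmox1) by 0.96 (SE 0.07) and sulfiredoxin (Srxn1) by 0.63 (SE 0.05). Prdx3 (-0.27) and Gstp1 (-0.42), named after their values were seen, fell. Hmox1 is also expressed by macrophages, whose markers were higher in the same hearts. In these hearts 9 of 27 immediate early genes rose and 1 fell (camera adjusted p = 0.00897, and adjusted p = 0.489 with an estimated correlation).

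Among genes of calcium handling and ion channels 24 of 41 fell and 5 rose (24 and 6 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.51e-08). Kcnip2, an accessory subunit of the transient outward potassium channel, fell by 1.74 on the log2 scale (SE 0.07, adjusted p = 1.45e-07). The pacemaker channel gene Hcn2 fell by 1.72 (SE 0.09), the T-type calcium channel gene Cacna1g by 1.41 (SE 0.08) and the calcium channel subunit gene Cacna2d1 by 0.80 (SE 0.05). Kcne1, a subunit of the slow delayed rectifier, fell by 1.73 (SE 0.13) and Abcc9, a subunit of ATP-sensitive potassium channels, by 0.89. The 5 that rose were Kcnd2 (0.70), a pore subunit of the transient outward channel, the calcium pump regulator Sln (0.76), and, named after their values were seen, Scn4b (1.09), Trdn (0.36) and Atp1b1 (0.20). In the same hearts the macrophage markers were higher (median 1.30), and 9 of 27 immediate early genes rose (camera adjusted p = 0.00897, and adjusted p = 0.489 with an estimated correlation).

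In the adult sarcomere list 4 of 25 rose and 6 fell (4 and 6 adjusted over the list alone), with a median of -0.04. Set against other genes the list was not shifted (camera adjusted p = 0.673), while it passed downward with fry (adjusted p = 0.000317). The list holds Myom2, whose fall was much larger than the others named here. Its fry result without Myom2 was not computed, so a fall shared by the members is not shown. The groups overlapped in the mean over members, relative to WT: it was -0.09 in WT replicate 4, below the -0.08 to -0.04 of the KO hearts. Myom2, a protein of the M-band, fell by 1.71 on the log2 scale (SE 0.06, adjusted p = 7.71e-08), tropomodulin 1 (Tmod1) by 0.34 and troponin C (Tnnc1) by 0.28, while desmin (Des) rose by 0.27. Myh6, the adult heavy myosin chain, differed by -0.08 (adjusted p = 0.219 in limma, and 0.0249 with an intensity trend and robust variances, within a range of 0.0249 to 0.368 over the alternatives). In the fetal and stress gene list 6 of 23 rose and 5 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.223). Beside Tnnt1 and Ccn2, skeletal actin (Acta1) rose by 1.27 (SE 0.11) and Xirp2 by 0.60, and Myocd, a coactivator of serum response factor, fell by 1.18 (SE 0.06). The stress markers Myh7 (-0.16, adjusted p = 0.0948), Nppa (0.51, SE 0.25, adjusted p = 0.178) and Nppb (0.04, adjusted p = 0.858) did not pass. Without WT replicate 4, whose Nppa level was 11.25 against 12.37 to 12.56 in the other WT hearts, Nppa differed by 0.20 (adjusted p = 0.14, range 0.0573 to 0.316 over the alternatives). Nppb took either sign when single arrays were left out, from -0.03 without KO replicate 4 to 0.13 without WT replicate 4. Differences were narrow among the brightest genes, with an SD over genes of 0.05 at WT levels above log2 13, where some sarcomere genes lay. It was 0.18 at 12 to 13 and 0.27 at 11 to 12.

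In the tricarboxylic acid cycle list 10 of 20 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.000134). Fumarase (Fh1) fell by 0.39 on the log2 scale (SE 0.04), the succinyl-CoA ligase subunit gene Suclg2 by 0.38, malate dehydrogenase (Mdh2) by 0.37 and Sdhb by 0.26, while Got1 (0.15), named after its values were seen, rose. Of the 2 clusters of Suclg2 the dimmer did not pass (-0.15). In branched-chain amino acid catabolism 12 of 24 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.18. The list's adjusted p was 0.000185, and adjusted p = 0.148 with an estimated correlation. Acat1 fell by 0.55 (SE 0.05), Ivd by 0.52, Bckdhb by 0.50 and Pccb by 0.47, and Bcat2 (0.47), named after its values were seen, rose. Among subunits of oxidative phosphorylation 19 of 76 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.09. The list's adjusted p was 0.000817, and adjusted p = 0.603 with an estimated correlation. Its mean over members, relative to WT, was -0.01 in KO replicate 4, within the WT range of -0.01 to 0.01, and -0.13 to -0.10 in the other KO hearts. The complex I gene Ndufs1 fell by 0.38 and the ATP synthase gene Atp5l by 0.36, with 3 of its 5 clusters passing, and Ndufa5 rose by 0.42. In the same KO hearts macrophage markers were higher by a median of 1.30, and 9 of 27 immediate early genes rose and 1 fell (camera adjusted p = 0.00897, and adjusted p = 0.489 with an estimated correlation).

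In fatty acid uptake and beta-oxidation 12 of 29 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.06. The list's adjusted p was 0.00343, and adjusted p = 0.555 with an estimated correlation. In the same hearts the macrophage markers had a median of 1.30, and 9 of 27 immediate early genes rose (camera adjusted p = 0.00897, and adjusted p = 0.489 with an estimated correlation). The carnitine transporter gene Slc22a5 fell by 0.74 on the log2 scale (SE 0.06), the acyl-CoA dehydrogenase genes Acad12 and Acads by 0.73 and 0.63, and the acyl-CoA synthetase gene Acsl6 rose by 0.77. In the PPAR alpha response list 7 of 23 fell and 2 rose (8 and 4 adjusted over the list alone, camera adjusted p = 0.492). Fitm1, a gene of lipid droplet formation, fell by 1.27 (SE 0.07), Acot2 by 0.63 and Fitm2 by 0.27. The uncoupling protein gene Ucp3 rose by 0.97 (SE 0.11), and so did the lipid droplet gene Plin5 (0.29), named after its values were seen. Acot2 has close relatives whose shared hybridisation was not excluded. Among genes of triglyceride synthesis, storage and lipolysis 8 of 26 rose and 3 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.108). The lipase genes Pnpla2 and Lipe rose by 0.37 and 0.36, while Dgat1, which makes triglyceride from diglyceride, fell by 0.66 (SE 0.05), Gpat3 by 0.42 and Agpat2, named after its values were seen, by 0.31.

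The transcriptional regulators of these pathways did not move together. Of 23 regulators of mitochondrial gene expression 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.965). Ppard rose by 0.45 (SE 0.05) and the mitochondrial transcription factor gene Tfam by 0.43 (SE 0.11, adjusted p = 0.0183), and Rxrg fell by 0.24 and Polrmt by 0.21. Tfam did not pass without WT replicate 3 (0.38, adjusted p = 0.051) or without KO replicate 1 (0.41, adjusted p = 0.0545), within a range of 0.00681 to 0.0545 over the alternatives. The others were, named after their values were seen, Tfb2m (0.28), which rose, and Ppargc1b (-0.33), which fell. Ppargc1a (0.22, SE 0.11, adjusted p = 0.19, and 0.12 without WT replicate 2), Ppara (0.10, adjusted p = 0.622, and -0.04 without WT replicate 2) and the pyruvate dehydrogenase kinase gene Pdk4 (0.21, adjusted p = 0.115) did not pass. Pdk4 passed without KO replicate 4 (0.27, adjusted p = 0.0412) and with array weights (0.24, adjusted p = 0.0333), within a range of 0.0333 to 0.269 over the alternatives. In glycolysis and pyruvate use 10 of 29 fell and 5 rose (14 and 6 adjusted over the list alone, camera adjusted p = 0.184), and the phosphofructokinase genes Pfkl (-0.44) and Pfkm (-0.37) were among those that fell. Glycogen metabolism had 5 of 20 higher and 6 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.869), with Ugp2 at 0.70 and Ppp1r3d at -0.77. In fatty acid synthesis and desaturation 3 of 19 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.842), among them Scd4, Mlxipl (-0.61) and fatty acid synthase (Fasn, -0.35). In cholesterol synthesis and uptake 4 of 18 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.108). Without the dim filter this list passed camera downward (adjusted p = 0.0472), within a range of 0.00269 (fry) to 0.603 (estimated correlation) over its alternatives. Hsd17b7 fell by 1.52 (SE 0.06, adjusted p = 1.37e-07), Hmgcs1 by 0.51, Cyp51 by 0.45 and Insig1, named after its values were seen, by 0.42, and Fdft1 rose by 0.30.

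Among HDAC3 corepressor partners and other deacetylases 6 of 19 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.165). Beside Hdac3 itself, Hdac11 fell by 0.61 and Hdac6 by 0.37, and the corepressor subunit gene Tbl1xr1 rose by 0.53, as did Tbl1x (0.32), named after its values were seen. Of the thyroid hormone and liver X receptor list 6 of 20 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.871), with Kcnd2 higher and Hcn2, Abca2 (-0.41) and Smpdl3a (-0.43) lower. In the circadian clock list 3 of 20 rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.812). The repressor Nfil3 rose by 0.86 (SE 0.11), Dbp fell by 0.41, Per3 by 0.38 and Bhlhe41 by 0.27, and Nr1d1, which encodes the HDAC3-recruiting receptor Rev-erb alpha, differed by -0.10 (adjusted p = 0.471, with -0.02 without WT replicate 2 and -0.17 without WT replicate 3). The other rises, Arntl (0.67) and Csnk1e (0.18), were named after their values were seen. In the autophagy list 9 of 28 rose and 5 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.407), with Gabarapl1 at 0.89, Cish at -0.62 and Map1lc3a at -0.58. In the p53 and cell death list 7 of 26 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.559), with Trp53inp1 at 0.75 and Bnip3 at 0.63.

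**Figure D2:**
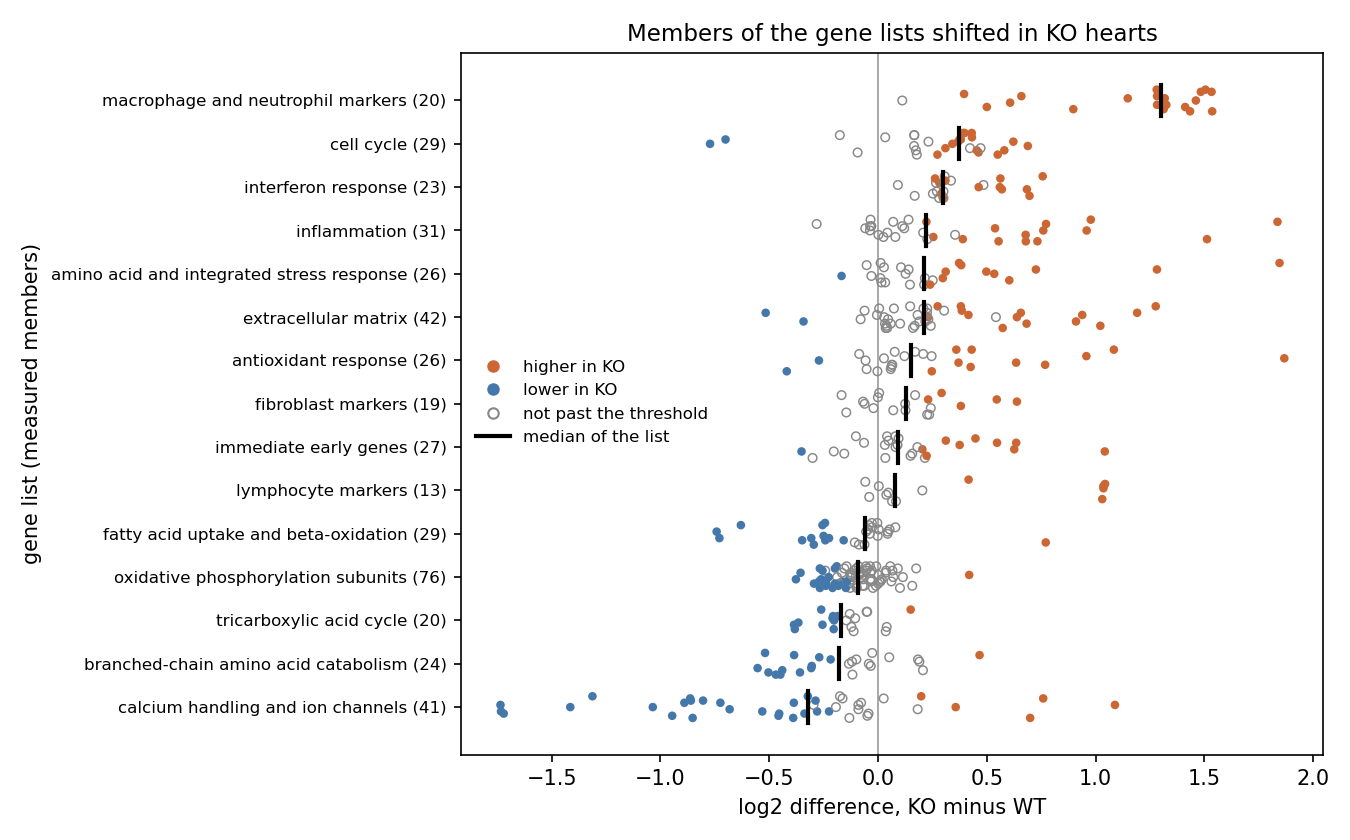
Log2 difference, KO minus WT, of each measured member (points) of the 15 gene lists shifted at the preset correlation, with filled points for members past the threshold and black bars for the list medians. The macrophage list lies farthest to the right (median 1.30) and the calcium and channel list farthest to the left (median -0.32).

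The other marker lists of cell types did not pass camera with all arrays, although single members changed. Endothelial markers had 3 of 21 higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.141), including Rgcc (0.38), and the list reached an adjusted p of 0.0169 without WT replicate 2 (adjusted p = 0.635 with an estimated correlation and all arrays). Adipocyte markers had 3 of 14 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.141), with Lipe, Acsl5 (0.42) and Thrsp (0.42), and reached 0.0253 without WT replicate 2 and 0.0297 with the stricter dim filter (adjusted p = 0.603 with an estimated correlation). Smooth muscle and pericyte markers had 1 of 15 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.965), which were Des, Abcc9 and Smtn (-0.40). Atrial myocyte markers had 2 of 16 higher and 1 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.545), with Sln and Pam (0.34) among them. Their mean over members was -0.68 in WT replicate 4 and -0.02 to 0.43 in the other WT hearts, and the difference in this mean was 0.20 with all arrays and -0.03 without WT replicate 4. Skeletal muscle genes had 2 of 18 higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.932), including Acta1, Mybpc1 (0.39) and Ckm (-0.25). Epicardial markers had 1 of 11 higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.335), which was Krt18 (0.66). Of 11 neuron and Schwann cell markers 0 passed in limma (0 adjusted over the list alone, camera adjusted p = 0.141), and 2 had an unadjusted p under 0.05.

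Erythroid and platelet markers had 1 of 7 higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.869). The platelet chemokine gene Pf4 rose by 1.35 (SE 0.06, adjusted p = 6.47e-07), and the heme synthesis genes Alas2 and Fech fell by 0.33 and 0.26 on the log2 scale. The platelet integrin gene Itga2b differed by -0.13 (adjusted p = 0.289), and macrophage markers rose by a median of 1.30 in the same hearts. The median (-0.07), mean (0.09) and direction of the test (down) differed in sign for the erythroid and platelet list. They also differed for fatty acid synthesis (0.02, -0.10, down), regulators of mitochondrial gene expression (0.00, 0.01, down), skeletal muscle (-0.01, 0.05, up) and the thyroid hormone and liver X receptor list (0.03, -0.04, down). As signs of tissue handling, 9 of 27 immediate early genes rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00897), with Ier5 at 1.04, Ier3 at 0.64 and Egr2 at 0.45, and Ccn1, named after its values were seen, at -0.35. This list had adjusted p = 0.489 with an estimated correlation, and 0.0505 without WT replicate 3. Of 15 heat shock genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.141), with Dnajb4 at 0.59 and Hspa5 at 0.43, and the list reached 0.043 without WT replicate 4 and 0.0143 without KO replicate 2 (adjusted p = 0.751 with an estimated correlation). The sex chromosome list had 3 measured members and was not tested as a list.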

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

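The tests of lymphoid tissue, of the macrophage share, of the myocyte share, of diluted myocyte RNA, of atrial tissue and of both explanations for the clock genes were chosen only after the result was seen, and the test of blood was written after the erythroid list, but not the haemoglobin clusters, had been seen. The 8 arrays can be divided into 4 and 4 in 35 ways. For the number of changed genes, 1 of the 35 splits, the real one, gave as many: 3683 genes against at most 0 in the others. By the rule written beforehand this count is not put down to chance division. The other splits mix the groups, so the group difference adds to their spread and lowers their counts, and 1 of 35 is the smallest share possible. For the number of shifted lists, 6 of the 35 splits gave as many, with 15 lists in the real split and up to 21 in another. By the rule written beforehand, chance division is therefore not excluded for that number. The 5 other splits with as many lists each kept 3 arrays of a group together, so they still held part of the group difference. The 18 splits with 2 arrays of each group on each side shifted at most 9 lists.

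Macrophage markers were higher in KO hearts, with 19 of 20 measured members past the threshold and a median of 1.30. Blood left in the KO hearts would raise haemoglobin, but the 8 haemoglobin clusters had a mean of -0.13 (mean plus 2 standard errors 0.00), and the 3 brightest adult clusters were at -0.28, -0.37 and -0.21. Lymphoid tissue in the samples would raise lymphocyte-restricted genes. For 7 such genes the median was 0.04 and the highest upper 95% limit was 0.39. These 7 were picked after the list was seen, from members that had not passed, and Cd4, which rose, was left out. They cannot decide on lymphoid tissue, and show only that these genes did not rise as the macrophage markers did. A larger share of macrophages in the KO tissue and higher expression per macrophage cannot be told apart, since the 19 markers that rose are the pattern itself and bear on neither.

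In the calcium handling and channel list 24 of 41 members fell, with a median of -0.32 over the whole list. A lower share of myocytes alone would raise the markers of every other cell type alike. The macrophage median of 1.30 (SD of members 0.43) lay at least 1.17 above the medians of the endothelial, fibroblast, smooth muscle, adipocyte, epicardial and neuron lists. This argues only against a lower myocyte share as the source of both changes. Medians of the other lists ran from 0 (smooth muscle) to 0.13 (fibroblast), so a smaller loss of myocytes beside the rise of macrophage markers stays open. RNA of added macrophages diluting that of myocytes would lower the members by 1 common amount, but no more than 14 of the 41 had 95% intervals that share a value, and Kcnd2 (0.70) and Scn4b (1.09, named after its values were seen) rose, which argues against dilution as the whole fall. Dilution as part of it stays open: 20 of 25 sarcomere genes had a lower 95% limit above -0.32, but 8 of 12 under a WT level of log2 12. That level limit was set after the 20 were seen, because differences of brighter genes were narrower. The SD over genes was 0.27 at levels of 11 to 12, 0.18 at 12 to 13 (90 genes) and 0.05 above 13 (14 genes). A smaller share of atrial tissue would lower atrial markers, yet the 16 measured had a median of 0.10, with 2 higher and 1 lower. Of the 13 outside the channel list, a limit that set aside Sln (0.76), 7 had a lower 95% limit above -0.32. Without WT replicate 4 the mean difference of the whole atrial list went from 0.20 to -0.03. A smaller atrial share is therefore not shown, and stays open. A smaller loss of myocytes, partial dilution and atrial share cannot be told apart here from an effect of HDAC3 loss on these genes in myocytes. A batch that follows the groups, an effect secondary to the state of the KO hearts and a change confined to conduction tissue were not tested.

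In the clock list Arntl (0.67) and Nfil3 (0.86) rose while Dbp (-0.41), Per3 (-0.38) and Hlf (-0.38) fell, and Arntl, Hlf, Clock and Cry1 were named after their values were seen. Hearts collected at different times of day could give this, and 8 genes in the opposite phase to Arntl had a median of -0.18 (SD 0.31), with 4 of them lower. Loss of HDAC3-dependent repression by Rev-erb could also raise Arntl, Clock, Cry1 and Nfil3, which had a median of 0.47 with 2 of the 4 past the threshold. The explanations cannot be told apart, since collection times are not given in the sources used here and the members of both gene sets moved unevenly.

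An array far from the other 3 of its group was seen in 19 of 418 groups of 4 values (named genes and list means), with a gap above 0.829 of the group's range, where chance gives about 1 in 20. Of these, KO4 was the distant array 6 times and WT2 6 times. In KO hearts the gap was 0.916 for Hdac3 (KO4 at 8.50, the others at 8.59), 0.951 for Ms4a6b (KO4 at 7.43, the others at 8.14 to 8.18), 0.862 for Postn (KO4), 0.846 for Oas2 (KO4), 0.892 for Usp18 (KO4), 0.836 for Ppara (KO4), 0.914 for Hdac6 (KO3) and 0.911 for Ccl7 (KO3). In WT hearts it was 0.949 for Hcn2 (WT3 at 7.09, the others at 7.36 to 7.38), 0.916 for Mlxipl (WT2), 0.875 for B2m (WT2), 0.871 for Mybpc1 (WT2), 0.934 for Abcc9 (WT2), 0.830 for Lum (WT1) and 0.862 for Smpdl3a (WT1). The WT list means of branched-chain amino acid catabolism (0.840) and fatty acid synthesis (0.843) had WT2 apart. For Nppa the gap was 0.851 (WT4 at 11.25, the others at 12.37 to 12.56) and for the atrial light chain Myl4 it was 0.841, with WT4 below the others at 12.27 to 12.51. Without WT replicate 4, Myl4 differed by 0.39 with an adjusted p of 0.00984, against 0.74 and 0.0822 with all arrays, and it passed with array weights as well (0.91, adjusted p = 0.0287, range 0.00984 to 0.195 over the alternatives).

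Outside the gene-level comparison, 296 of the 4593 clusters without a gene symbol changed in a limma fit of all clusters, 158 higher and 138 lower, or 6.44%. Among clusters with 1 gene symbol the share was 15.8%. The unnamed clusters were dimmer, with a median level of 4.71 against 6.07.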

How the results depend on the processing

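The list test without marker genes was chosen after seeing the data. Requiring at least 1.5-fold as well left 610 genes (359 higher, 251 lower), and an adjusted p under 0.01 left 2210 (961 higher, 1249 lower), by construction. Shifted lists numbered 6 with an estimated correlation and 23 with fry. The erythroid and platelet list turned up with fry (adjusted p = 0.0472, range 0.0472 to 0.984 over its alternatives). Of its 7 members only Pf4 (1.35) passed as higher, and 2 passed as lower. The list was not tested without Pf4, so a rise of erythroid or platelet markers as a set is not shown. The other scalings, filters, variance model, weights and cluster rules gave 3418 to 4529 genes and kept 3310 to 3635 of the 3683 where all or nearly all were tested, and the stricter dim filter kept all 3162 it tested. The share of higher calls was 43.8%, and from 36.4% with median centring to 48.1% with array weights. Leaving out 1 array gave 2871 genes (without KO replicate 1) to 3619 (without KO replicate 4), 13 to 17 lists and Hdac3 differences of -1.56 to -1.51. Pathway lists without genes of the marker lists gave 15. Same-numbered arrays did not deviate together (correlations -0.04, 0.03, -0.04 and 0.08) and 1 of 4 WT arrays correlated best with its own number. No pairing by number was therefore seen, though a pairing with little effect on expression would look the same. With the replicate number as a block, 3382 genes changed (1466 higher, 1916 lower), 3205 of them among the 3683, and 16 lists shifted, the heat shock list among them (adjusted p = 0.0477, range 0.0143 to 0.751 over its alternatives). Without detection calls, signal over background is unknown, and a dim gene that did not pass is not shown to be unchanged.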

Other observations

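Gene families were grouped by their symbols after the lists had been examined, so their tests and the test of Hdac3's neighbours were chosen after the result was seen. The genes given with values here were named after those values were seen. The test of channel genes was written before, and its bootstrap interval was added after. Of 19 families tested with camera, the Fc receptors, which bind antibodies, had the smallest adjusted p: 6 of 7 rose and 0 fell (adjusted p = 9.6e-07, and adjusted p = 0.0387 with an estimated correlation), among them Fcer1g (1.52), Fcgr2b (1.36) and Fcgr4 (0.95). Of the Toll-like receptors 6 of 8 rose and 0 fell, with Tlr7 at 1.69 and Tlr13 at 1.59 (adjusted p = 2.96e-05, and adjusted p = 0.0641 with an estimated correlation). In the Ms4a family 6 of 9 rose and 0 fell (adjusted p = 2.96e-05, and adjusted p = 0.0541 with an estimated correlation). Of 22 C-type lectins 8 rose and 0 fell, with Clec4a3 at 1.44 (adjusted p = 0.000126, and adjusted p = 0.0628 with an estimated correlation). Among 13 cathepsins 6 rose, led by Ctss (1.49) and Ctsc (1.00), and Ctsf (-0.42) fell (adjusted p = 0.011, and adjusted p = 0.367 with an estimated correlation). These families have members expressed by macrophages, whose markers rose by a median of 1.30 in the same hearts. Their direction was the same with quantile normalisation and with median centring.

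Some families outside the immune genes moved as well, in the same hearts in which macrophage markers had a median of 1.30 and 9 of 27 immediate early genes rose (camera adjusted p = 0.00897, and adjusted p = 0.489 with an estimated correlation). Of 68 genes with Rpl or Rps symbols 20 rose and 2 fell, with a median of 0.12 (adjusted p = 3.49e-06, and adjusted p = 0.187 with an estimated correlation), and 16 rose with median centring. This symbol match, meant for cytosolic ribosomal proteins, also takes in any measured Rps6k genes, which encode kinases. Tubulins had 7 of 12 higher and 0 lower, with Tubg2 at 0.90 and Tubb6 at 0.55 (adjusted p = 0.000126, and adjusted p = 0.0641 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, had 6 of 14 higher and 0 lower, with Cars at 0.42 and Nars at 0.35 (adjusted p = 0.0405, 0.0525 with median centring, and adjusted p = 0.178 with an estimated correlation). Their mitochondrial counterparts had 0 of 16 higher and 4 lower (adjusted p = 0.213), and the difference between these families was not tested. Single large falls included the phosphodiesterase genes Pde1c (-1.34) and Pde7b (-1.01) and the ventricular transcription factor gene Irx4 (-1.14). Their families did not pass: phosphodiesterases had 2 of 24 higher and 4 lower (camera adjusted p = 0.313). Irx and Tbx factors had 2 of 18 higher and 4 lower (camera adjusted p = 0.635). Those that rose included Pde7a (0.80), Pde3b (0.67) and Tbx15 (0.82).

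The fall of channel genes was followed outside the fixed list on 74 other genes with Kcn, Cacn, Scn or Hcn symbols. Among them Kcnd3os, Kcnmb4os1 and Kcnmb4os2 are, by their symbols, opposite-strand transcripts and not channel subunits. Camera gave a p of 0.66 for them as a set (0.86 with an estimated correlation), with 2 higher and 6 lower. By the rule written beforehand, a median that was not negative counted against an extension of the fall, and the median was 0.02. The 95% bootstrap interval added later, from -0.02 to 0.03, leaves the sign of that median open. Their median WT level was 5.28, against 8.65 in the fixed list and a dim limit of 4.50, and whether dim signal hid a fall was not tested. Kcnk6 (0.69) and Kcnab2 (0.52) rose, and Kcng2 (-0.47) and Cacna1s (-0.44) were among those that fell.

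Donor-strain DNA carried along with the targeted gene could change the genes next to Hdac3. Of the 50 measured genes nearest to it in order along the chromosome, 11 changed (22%, upper 95% limit 36%), 3 higher and 8 lower, against 24.6% of the other genes tested (one-sided Fisher's exact test, p = 0.718). No excess was seen, and the interval leaves room for a modest one.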
